A study of Lathyrus oleraceus with 120 samples.

How the data were processed

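The samples were leaves of 4 field pea (Lathyrus oleraceus) genotypes, named 11HP302-12HO-1, WHARTON, TWILIGHT and OZP1604 in the labels, collected after inoculation with Peyronellaea pinodes, a fungus that causes ascochyta blight, or from control plants. Inoculated leaves were taken at 0, 6, 24, 48, 72 and 96 hours post inoculation (hpi) and control leaves at 0, 6, 24 and 48 hpi, which gave 40 groups of 3 libraries. The labels do not say whether the 3 replicates of a group were separate plants or pots, so the p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, plants grew under 16 h of light and 8 h of dark at 24 and 15 °C, were moved 1 day before inoculation to a chamber with 12 h of light and of dark at 15 °C, and were inoculated at the 3 to 4 node stage. Per the same protocols, RNA came from 100 mg of leaf with 2 extraction kits, whose assignment to samples is not stated, and the libraries were strand-specific.

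The authors deposited a table of raw read counts for 44756 pea genes in the 120 libraries, which per the file headers was counted from sorted alignments. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here, and the submitters' processing notes name FastQC, Salmon, DESeq and sleuth without versions. Genes with near-identical copies or antisense partners are therefore uncertain in how their reads were shared, as in the light-harvesting, ribosomal, histone and chalcone synthase families. The authors also deposited 24 tables of significant genes, for the 4 genotypes at 6 times, with q-values and effect sizes on the natural log scale. These q-values and natural log effects have the column names of a sleuth test, list only genes with a q-value under 0.05, and do not name the control used at 72 and 96 hpi. The authors' tables also pair pea genes with Medicago truncatula descriptions, 1761 of them with an Arabidopsis match, and with Gene Ontology (GO) terms. A reference list of current gene symbols shared no identifier with the count table and was not used, so gene names here are the authors' descriptions and coordinates are not given.

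Counts were analysed as deposited, and 0 entries of the table named no gene. The library totals ran from 25 to 6185453 counts with a median of 3216703. In all, 3 libraries held under 200000 counts, and the lowest total of the others was 396976. Of the 31119 genes with any count, filterByExpr in edgeR 4.0.16 (R 4.3.3; minimum count 10, minimum total 15) kept 21042 genes. Library sizes were scaled by the trimmed mean of M-values (TMM). A model with 1 mean per group, 80 residual degrees of freedom and a trended dispersion was fitted by edgeR's quasi-likelihood method. Each p-value was adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All groups entered 1 fit so that they shared an estimate of the spread, and standard errors (SE) of log2 fold changes were taken from the F statistic.

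Inoculated and control libraries were compared at 0, 6, 24 and 48 hpi, and inoculated libraries at 72 and 96 hpi were compared with the 48 hpi control, for each genotype and for the equal-weight mean of the 4 genotypes. Because no control was taken at 72 or 96 hpi, elapsed time and inoculation cannot be told apart there. An F-test with 3 degrees of freedom asked whether the difference varied among genotypes, and 2 more F-tests compared control libraries among genotypes and among times. The difference at 6, 24 and 48 hpi minus that at 0 hpi was also tested. The same subtraction for 72 and 96 hpi was added after seeing the data.

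The sample titles come in 2 word orders, which divide the libraries into a set of 48 (inoculated at 0, 24, 72 and 96 hpi) and a set of 72 (all controls and inoculated at 6 and 48 hpi). The labels do not say what the 2 orders stand for. Inoculated and control libraries lie in the same set at 6 and 48 hpi, and in different sets at 0, 24, 72 and 96 hpi, where set and inoculation cannot be told apart. Values minus the 0 hpi difference therefore stand beside part of those at 24, 72 and 96 hpi, and a value there without a subtracted one also holds any difference between the sets. The averaged edgeR test loses its meaning for many genes with 0 counts in whole groups, because such a group's fitted value can offset the rest. Unless marked edgeR, subtracted values of single genes are from limma-voom (limma 3.58.1), added after seeing the data. An averaged fold change of a gene with 0 counts in a whole group has no exact size either, because that group's fitted value depends on the prior count, and the limma-voom value stands beside it.

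Levels are CPM values, each count as a share of the TMM-scaled library total on the usual CPM scale, as the mean and SD over the libraries of all 4 genotypes, so the SD includes differences among genotypes. The 3 libraries under 200000 counts were left out of these levels but not of the tests. The levels then rest on 11 control libraries at 0 and 48 hpi, 11 inoculated libraries at 6 hpi and 12 libraries elsewhere. Intervals for counting error are not given, because reads without molecular identifiers are not independent molecules.

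The rule for named genes, the tests and 24 gene lists were fixed before the data were examined. The rule took, in each averaged comparison after 0 hpi, the 10 called genes with the largest rise and the 10 with the largest fall that had a fitted mean of at least 5 CPM, 1 sign in all 4 genotypes and a description. At 0 hpi it took 5 and 5. From each list it took the 2 called members with the largest rise and the 2 with the largest fall, and from each genotype F-test the 5 genes with the smallest p. Lists were matched to pea genes through the authors' Arabidopsis matches and descriptions. Another 17 lists drawn from words in the descriptions were added after the data were seen.

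Of 13430 genes with a description or a match, 69 appear in no deposited table of significant genes. Members of every list were therefore chosen by the study on these samples, and their counts are not independent evidence of direction. Lists with at least 3 members were tested with camera (preset correlation 0.01, on log2 CPM with a prior count of 3), adjusted over lists and the 6 averaged comparisons, and again with an estimated correlation. GO terms with 10 to 500 tested genes were tested for an excess of called genes by one-sided Fisher's exact tests against all tested genes with a term.

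The alternatives chosen beforehand were DESeq2's size factors, no filter on low counts, DESeq2 1.42.0 or limma-voom tests, a fit of only the libraries compared, leaving out each replicate number of each treatment in turn, a replicate block, and for 72 and 96 hpi the 24 hpi control or the mean of the 0, 24 and 48 hpi controls. Fits without the 3 libraries under 200000 counts, without the 5 libraries in which 20 genes took over 40% of the counts, and without 3 libraries that stood apart from their groups on the principal components, were added after seeing the data. The last 3 were TWILIGHT inoculated 1 at 0 hpi, TWILIGHT control 2 at 6 hpi and 11HP302-12HO-1 inoculated 3 at 6 hpi. Other splits of the samples were counted with limma-trend on log2 CPM, with at most 100 splits each.

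The edgeR, limma-trend and camera tests, but not the limma-voom, DESeq2 and GO term tests, were first tested on simulated data. Counts were drawn from gene means without the real group differences, with 200 genes changed. For the averaged 24 hpi comparison, run on 19167 genes, edgeR called 185 genes, 11 of them not changed. It recovered 75% of the 2-fold and 99% of the 4-fold changes. For WHARTON alone at 24 hpi, with 3 libraries against 3 and 19167 genes, it recovered 7% of the 2-fold and 64% of the 4-fold changes. The authors' GO enrichment summaries and repeat copies of the annotation tables were not used here.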

Results

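Messenger RNA was measured by strand-specific RNA sequencing in leaves of 4 field pea genotypes after inoculation with Peyronellaea pinodes, with 3 libraries in each of 40 groups. Inoculated leaves were sampled at 0 to 96 hpi and control leaves at 0 to 48 hpi. Library totals had a median of 3216703 counts and a maximum of 6185453. The 3 libraries under 200000 counts all belonged to 11HP302-12HO-1. They held 25 counts in control 1 at 0 hpi, 33327 in control 3 at 48 hpi and 130308 in inoculated 2 at 6 hpi. The remaining 48 hpi controls of 11HP302-12HO-1 held 396976 and 532772 counts. The 20 most abundant genes took a median of 27.8% of the counts in control libraries at 0 hpi and 19.4% in inoculated libraries at 0 hpi, against 9.14% to 16.3% in the groups after 0 hpi. This share was 60.6% and 53.2% in TWILIGHT controls 1 and 2, 45.1% in WHARTON control 3 and 42.6% in OZP1604 control 3 at 0 hpi, 84% in the library of 25 counts, and at most 33.1% in all other libraries.

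**Figure D1:**
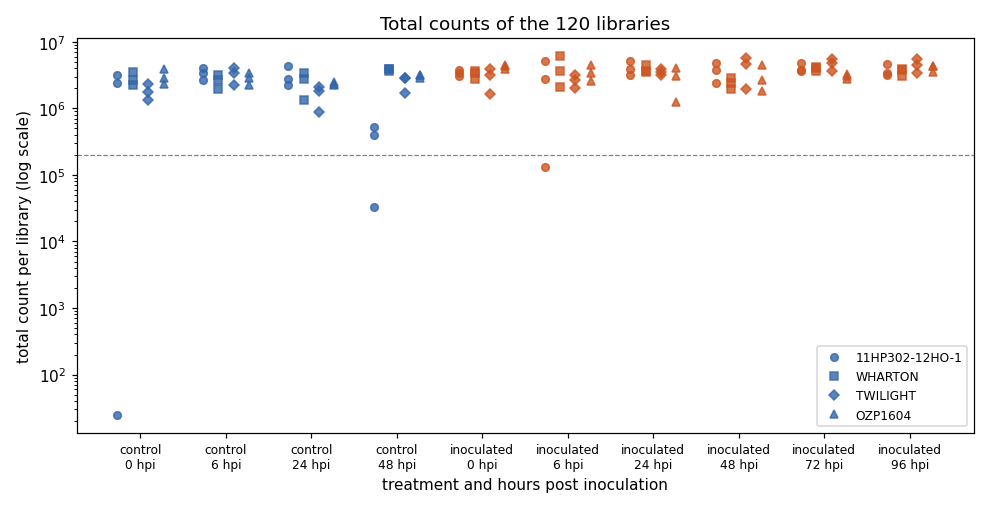
Total counts of each library on a log axis, by treatment and hours post inoculation, with 1 symbol per genotype and a dashed line at 200000 counts. The 3 libraries below the line held 25, 33327 and 130308 counts, and the median over the 120 libraries was 3216703.

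At 0 hpi, the moment of inoculation, ribosomal protein genes and part of the photosynthesis genes were lower in the inoculated than in the control libraries, and a proton pump gene and single cell wall genes were higher. The ribulose bisphosphate carboxylase large subunit (Psat5g168040) measured 408 ± 426 CPM in control leaves (SD, n = 11) and 23.3 ± 23.9 CPM in inoculated leaves (SD, n = 12), a log2 fold change of -4.05 ± 0.62 (SE, edgeR adjusted p = 1.12e-07). A photosystem II D1-like gene (Psat3g186560) measured 177 ± 233 and 6.11 ± 4.15 CPM (log2 fold change -3.89 ± 0.56). Without the 5 libraries in which 20 genes took over 40% of the counts, these values were -3.11 ± 0.64 and -2.95 ± 0.6 (edgeR adjusted p = 8.21e-05 and 5.85e-05). The 60S ribosomal protein L39-3 (Psat0s3660g0040) fell by 3.07 on the log2 scale, from 44.6 ± 20.9 to 6.17 ± 5.14 CPM. In the other direction, plasma membrane ATPase 4 (Psat3g162440), a proton pump, measured 0.686 ± 0.684 and 16.6 ± 6.1 CPM (log2 fold change 5.22 ± 0.52, edgeR adjusted p = 1.21e-13). The control libraries of 1 genotype held 0 counts of it, and limma-voom gave 3.97 (limma-voom adjusted p = 6.28e-12). Proline-rich protein 4 (Psat7g138320) measured 4.02 ± 3.82 and 165 ± 229 CPM.

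All 7 tested members of the photosynthesis list were lower at 0 hpi, and all 7 adjusted over the list alone (camera adjusted p = 0.00177, adjusted p = 0.307 with an estimated correlation). Chlorophyll a-b binding protein 215 (Psat2g004560), an antenna protein of photosystem II, measured 62100 ± 25100 CPM in control leaves and 18700 ± 9540 CPM in inoculated leaves. In the wider set of 71 photosynthesis genes picked by description after the data were seen, 13 were higher and 17 lower (camera adjusted p = 0.916), or 6 and 18 without the 5 libraries of high share. Among those higher was an AB80 gene (Psat7g091520), at 157 ± 131 and 795 ± 392 CPM (log2 fold change 2.67 ± 0.53, edgeR adjusted p = 2e-05). Of 19 phenylpropanoid genes 7 were higher, also 7 adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.477 with an estimated correlation). A phenylalanine ammonia-lyase gene (PAL, Psat3g023040), the entry enzyme of that pathway, measured 8.15 ± 4.62 and 66.3 ± 83.3 CPM. Pectinesterase PME3 (Psat4g165320) measured 15.4 ± 6.72 and 77.7 ± 49.4 CPM. Of 10 genes for wall inhibitors and callose 6 were higher (6 adjusted over the list alone, camera adjusted p = 0.00696, adjusted p = 0.256 with an estimated correlation). Of 23 isoflavonoid genes 5 were higher (4 adjusted over the list alone), and of 38 genes for pathogenesis-related (PR) proteins 6 (4 adjusted over the list alone). Without the 5 libraries of high share these counts were 9 and 11. The phenylpropanoid count was 5 and that of wall inhibitors 6. TWILIGHT inoculated 1 lay at 29.09 on the first principal component, against -94.64 to -19.08 for the other 11 inoculated libraries at 0 hpi. In a fit without it and the 2 libraries apart at 6 hpi, 3 isoflavonoid genes were higher, and 3 PR genes were higher and 3 lower. These list members were chosen by the study on these samples, so the counts are not independent evidence of direction.

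In all, edgeR called 8052 genes at 0 hpi, 4485 higher and 3567 lower. Without the 5 libraries of high share it called 6591, of which 6178 were among the 8052. Without the 3 apart libraries it called 7787, of which 7313 were among the 8052. With all libraries the median log2 fold change of all tested genes was 0.103, or 0.115 with DESeq2's size factors. The ribosome had the smallest p among GO terms of the lower genes, with 173 of 385 genes (Fisher's exact adjusted p = 1.09e-41). The inoculated and control libraries at 0 hpi lie in different title sets. Over the 8052 called genes the 0 hpi differences correlated across genes at r = 0.77 with those at 24 and at 72 hpi, 0.6 with 96 hpi, 0.13 with 6 hpi and -0.19 with 48 hpi. Genes are not independent replicates.

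At 6 hpi, defence genes rose and photosynthesis genes and single genes of the leaf surface fell, with both treatments in 1 title set. Alpha-dioxygenase 1 (Psat0s3643g0040), an enzyme that oxidises fatty acids in defence, measured 2.26 ± 4.7 CPM in control leaves (SD, n = 12) and 132 ± 145 CPM in inoculated leaves (SD, n = 11), a log2 fold change of 6.18 ± 0.88 (SE, edgeR adjusted p = 7.83e-08). A protease inhibitor (Psat4g107840) measured 6.09 ± 13.9 and 114 ± 64.6 CPM. The transporter NRT1/PTR FAMILY 7.1 (Psat6g142760) measured 2.69 ± 3.67 and 80.7 ± 50.3 CPM. A germin-like protein (Psat4g182080) fell to 109 ± 86.2 CPM (log2 fold change -3.2 ± 0.41, edgeR adjusted p = 4.67e-09). The 3-ketoacyl-CoA synthase 6 (Psat6g228120), an enzyme of wax synthesis, fell from 147 ± 73.4 to 15.8 ± 16.5 CPM. Glycerol-3-phosphate acyltransferase 1 (Psat5g183160) fell from 9.18 ± 5.16 to 0.822 ± 0.925 CPM.

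Of the 23 genes on the isoflavonoid and pisatin list, 12 rose at 6 hpi and 0 fell (12 adjusted over the list alone, camera adjusted p = 1.01e-08, adjusted p = 0.223 with an estimated correlation). Pisatin is the phytoalexin, an antimicrobial compound, of pea. Pterocarpan synthase 1 (Psat3g067480), of the pterocarpan branch of that pathway, rose from 11.5 ± 12.5 to 74.6 ± 48.2 CPM (log2 fold change 2.84 ± 0.6), and vestitone reductase (Psat3g116280) from 44.1 ± 34.7 to 241 ± 90.2 CPM. PR genes rose in 15 of 38 cases and fell in 2 (20 and 2 adjusted over the list alone, camera adjusted p = 1.18e-08, adjusted p = 0.201 with an estimated correlation). Among them a beta-1,3-glucanase (Psat1g161880) measured 12.1 ± 11.1 and 82.1 ± 70.4 CPM. WRKY transcription factors, regulators of plant defence, rose in 25 of 45 cases and fell in 5 (28 and 5 adjusted over the list alone, camera adjusted p = 1.16e-06, adjusted p = 0.288 with an estimated correlation). WRKY75 (Psat3g160600) rose from 2.95 ± 2.9 to 22.6 ± 9.17 CPM. Jasmonate genes rose in 6 of 8 cases (6 adjusted over the list alone, camera adjusted p = 0.00318, adjusted p = 0.288 with an estimated correlation). The repressor JAZ1 (Psat1g136080) had a log2 fold change of 1.37 ± 0.26. The study chose these members on these samples.

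All 7 photosynthesis genes fell at 6 hpi (7 adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.248 with an estimated correlation). The antenna protein AB80 (Psat7g091560) fell from 910 ± 467 to 222 ± 231 CPM and photosystem I subunit psaK (Psat0s1315g0080) from 1430 ± 441 to 434 ± 219 CPM. In the wider set of 71 photosynthesis genes 63 fell and 0 rose (63 adjusted over the list alone, camera adjusted p = 1.47e-21, adjusted p = 0.741 with an estimated correlation). Chloroplast terms led the GO terms of the lower genes, with 135 of 255 genes lower (Fisher's exact adjusted p = 5.42e-35). Response to oxidative stress led those of the higher genes with 34 of 107 (Fisher's exact adjusted p = 0.00336). The flavonoid and anthocyanin list was split, with 4 of 21 genes higher and 6 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.516). Anthocyanidin 3-O-glucosyltransferase 2 (Psat2g018880) fell by 2.89 on the log2 scale. Single-member lists rose too, with HSP70 (Psat3g182640) of the heat shock list at 1.17 ± 0.22 and the dehydration factor RD26 (Psat5g245440) at 1.37 ± 0.28 log2 units. Both wetting and touch markers rose, such as ZAT10 (Psat6g016400) at 1.42 ± 0.28. In all, 6333 genes were called at 6 hpi, 2753 higher and 3580 lower. The count was 7397 after subtracting the 0 hpi difference, where the median over all tested genes was -0.146, or -0.138 with DESeq2's size factors.

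At 24 hpi, PR proteins, isoflavonoid enzymes and glutathione transferases rose, and light-harvesting genes fell. PR-1C (Psat1g211480), a classic marker of pathogen attack, measured 0.863 ± 1.97 CPM in control leaves (SD, n = 12) and 154 ± 140 CPM in inoculated leaves (SD, n = 12), a log2 fold change of 8.63 ± 1.1 (SE, edgeR adjusted p = 6.26e-10). The 3 controls of 11HP302-12HO-1 held 0 counts of it, and limma-voom gave 7.2 (limma-voom adjusted p = 3.78e-05). Minus the 0 hpi difference it was 7.37 (limma-voom adjusted p = 0.0267), not called by edgeR and resting on groups with 0 counts. A 12-oxophytodienoate reductase (Psat2g190200), of a family with a jasmonate synthesis step, rose from 21 ± 27.6 to 846 ± 447 CPM (log2 fold change 5.85 ± 0.56). Its subtracted value was 6.34 (limma-voom adjusted p = 3.53e-05), with 0 hpi differences of -7.25 (OZP1604) to 6.41 (TWILIGHT). A proline-rich cell wall protein (Psat4g192640) fell from 326 ± 367 to 7.22 ± 16.7 CPM (log2 fold change -7.48 ± 1.25, edgeR adjusted p = 3.97e-07). CONSTANS-LIKE 7 (Psat2g054040), of a family of light and day-length regulators, fell from 30.1 ± 8.45 to 0.962 ± 1.1 CPM.

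Of the 23 isoflavonoid genes, 22 rose at 24 hpi and 4 rose after subtracting the 0 hpi difference (22 and 6 adjusted over the list alone). The camera adjusted p of the first was 2.57e-10, with adjusted p = 0.186 with an estimated correlation. Pterocarpan synthase 1 (Psat3g067480) rose from 1.75 ± 2.17 to 110 ± 172 CPM, with a subtracted log2 value of 5.5 (limma-voom adjusted p = 0.0404), which edgeR did not call. The median log2 fold change of these 23 genes was 2.17 at 24 hpi, and the same genes differed between control leaves at 6 and 0 hpi by a median of 2.51. Among PR genes 29 of 38 rose and 2 fell (29 and 3 adjusted over the list alone, camera adjusted p = 6.85e-11, adjusted p = 0.159 with an estimated correlation). After subtraction 7 rose. Phenylpropanoid genes rose in 14 of 19 cases (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.85e-05, adjusted p = 0.288 with an estimated correlation). After subtraction 5 rose and 1 fell. All 9 glutathione transferase and antioxidant genes rose (9 adjusted over the list alone, camera adjusted p = 8.53e-06, adjusted p = 0.122 with an estimated correlation). After subtraction 6 rose (7 adjusted over the list alone, camera adjusted p = 6.71e-09, adjusted p = 0.0452 with an estimated correlation). GSTU8 (Psat3g133720) rose from 7.67 ± 10.7 to 56.1 ± 23.9 CPM, and its subtracted value was 4.34 (limma-voom adjusted p = 7.87e-05). All members were chosen by the study on these samples.

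All 8 jasmonate genes rose at 24 hpi (8 adjusted over the list alone, camera adjusted p = 0.000149, adjusted p = 0.186 with an estimated correlation). After subtraction 4 rose (5 adjusted over the list alone). JAZ1 (Psat1g136080) had a subtracted value of 1.95 (limma-voom adjusted p = 0.00195). Both salicylate genes, PAD4 (Psat7g045480) and SAG101 (Psat1g079240), rose, with log2 fold changes of 1.64 ± 0.3 and 1.41 ± 0.23. All 6 senescence genes rose (6 adjusted over the list alone, camera adjusted p = 0.000348, adjusted p = 0.186 with an estimated correlation). After subtraction 5 rose (5 adjusted over the list alone). SAG21 (Psat6g164600) of that list rose from 42.7 ± 22.2 to 177 ± 62.3 CPM, with a subtracted value of 2.41 (limma-voom adjusted p = 1.05e-05). The kinase MPK3 (Psat7g223040), of the cascade below pattern receptors, rose from 38.9 ± 18.6 to 151 ± 54.9 CPM, with a subtracted value of 1.94 (limma-voom adjusted p = 2.71e-06). On that list 7 of 9 genes rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.38 with an estimated correlation), and 1 rose and 2 fell after subtraction (1 and 2 adjusted over the list alone). The gene that fell before subtraction (Psat7g091800) carries the description of the flagellin receptor FLS2. It fell by 3.42 on the log2 scale to 121 ± 66 CPM, with a subtracted value of -1.76 (limma-voom adjusted p = 0.00114). Polygalacturonase inhibitor PGIP1 (Psat3g047600), which blocks fungal pectin-degrading enzymes, rose from 0.556 ± 1.02 to 25.7 ± 20.6 CPM. On the wall inhibitor list 8 of 10 genes rose (8 adjusted over the list alone, camera adjusted p = 4.67e-08, adjusted p = 0.06 with an estimated correlation). At 0 hpi 6 of these 10 were already higher, and after subtraction 2 rose (3 adjusted over the list alone).

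All 7 photosynthesis genes fell at 24 hpi and all 7 after subtraction (7 and 7 adjusted over the list alone, camera adjusted p = 1.52e-07, adjusted p = 0.122 with an estimated correlation). Chlorophyll a-b binding protein 215 (Psat2g004560) fell from 39200 ± 22100 to 3530 ± 1440 CPM, with a subtracted log2 value of -2.11 (limma-voom adjusted p = 0.00103). Ribosomal proteins, picked by description after the data were seen, fell in 136 of 186 cases and rose in 9 at 24 hpi, and fell in 8 and rose in 3 after subtraction (137 and 9, then 2 and 2 adjusted over the list alone, camera adjusted p = 2.71e-10, adjusted p = 0.789 with an estimated correlation). L12-3 (Psat7g228520) fell from 170 ± 48.7 to 25.6 ± 12.3 CPM, with a subtracted value of 0.11 (limma-voom adjusted p = 0.83). The clock gene LATE ELONGATED HYPOCOTYL (LHY, Psat3g000720), which peaks around dawn, measured 26.9 ± 14.1 CPM in control and 163 ± 26.1 CPM in inoculated leaves. In all, 11396 genes were called at 24 hpi, 5996 higher and 5400 lower. After subtracting the 0 hpi difference 3972 were called, 1675 higher and 2297 lower. This count was 2083 without inoculated replicate 3 and 2603 without control replicate 3 of every group.

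At 48 hpi, isoflavonoid, phenylpropanoid, PR and glutathione transferase genes rose and chloroplast genes fell, with both treatments in 1 title set. Pterocarpan synthase 1 (Psat3g067480) measured 0.501 ± 0.69 CPM in control leaves (SD, n = 11) and 30.3 ± 15.6 CPM in inoculated leaves (SD, n = 12), a log2 fold change of 6.49 ± 1.05 (SE, edgeR adjusted p = 1.54e-06). Peroxidase P7 (Psat5g250040) measured 0.248 ± 0.351 and 20.3 ± 10.3 CPM (log2 fold change 6.8 ± 0.91). PGIP1 (Psat3g069920) measured 0.512 ± 0.814 and 52.4 ± 48.8 CPM (log2 fold change 7.61 ± 1.01). For each of these 3 genes the control libraries of 1 genotype held 0 counts, so the fitted folds have no exact size, and limma-voom gave 5.47, 5.08 and 5.68 (limma-voom adjusted p = 0.000563, 8.08e-06 and 0.000134). A pectinesterase (Psat7g011240) fell from 53.3 ± 39.6 to 3.97 ± 2.01 CPM (log2 fold change -3.69 ± 0.47, edgeR adjusted p = 3.58e-09). CONSTANS-LIKE 7 (Psat2g054040) fell from 38.8 ± 8.8 to 3.97 ± 1.47 CPM.

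On the isoflavonoid list 22 of 23 genes rose at 48 hpi (22 adjusted over the list alone, camera adjusted p = 1.47e-22, adjusted p = 0.0674 with an estimated correlation), with a median log2 fold change of 2.8. Of 19 phenylpropanoid genes 14 rose and 1 fell (15 and 3 adjusted over the list alone, camera adjusted p = 3.84e-13, adjusted p = 0.0939 with an estimated correlation). A PAL gene (Psat1g046920) rose from 4.96 ± 2.34 to 44 ± 11.3 CPM. Of 21 flavonoid genes 9 rose (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.16e-06, adjusted p = 0.101 with an estimated correlation). Of 15 monolignol genes, for building blocks of lignin, 5 rose (6 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.366 with an estimated correlation). A caffeoyl-CoA O-methyltransferase (Psat1g049080) rose from 39.4 ± 21.6 to 152 ± 49.9 CPM. Among PR genes 26 of 38 rose and 1 fell (28 and 2 adjusted over the list alone, camera adjusted p = 1.09e-14, adjusted p = 0.101 with an estimated correlation). PR-1C (Psat1g211480) rose from 0.832 ± 1.82 to 60.9 ± 95.5 CPM in the mean, with log2 fold changes of 6.67 to 8.52 in 3 genotypes and -0.35 in 11HP302-12HO-1. Endochitinase PR4 (Psat5g291720) rose to 41.8 ± 21.6 CPM. WRKY genes rose in 23 of 45 cases and fell in 2 (25 and 2 adjusted over the list alone, camera adjusted p = 2.98e-12, adjusted p = 0.144 with an estimated correlation). WRKY40 (Psat5g308000) rose from 2.99 ± 1.36 to 62.5 ± 23.3 CPM. Of 9 glutathione transferase and antioxidant genes 8 rose (8 adjusted over the list alone, camera adjusted p = 1.52e-12, adjusted p = 0.0575 with an estimated correlation). GSTU20 (Psat0s2210g0040) rose from 1.05 ± 1.26 to 31.3 ± 14.3 CPM. Members of these lists were chosen by the study on these samples.

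Jasmonate genes rose in 6 of 8 cases at 48 hpi (6 adjusted over the list alone, camera adjusted p = 9e-05, adjusted p = 0.186 with an estimated correlation). LOX3 (Psat4g168720), a lipoxygenase of jasmonate synthesis, measured 25.5 ± 5.48 and 79.5 ± 26.1 CPM. Ethylene genes rose in 4 of 9 cases (5 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.385 with an estimated correlation), including the response factor ERF-1 (Psat4g073120) with a log2 fold change of 2.25 ± 0.29. Photosynthesis genes fell in 6 of 7 cases (6 adjusted over the list alone, camera adjusted p = 0.00116, adjusted p = 0.302 with an estimated correlation). Chlorophyll a-b binding protein 215 (Psat2g004560) fell from 33700 ± 9900 to 12600 ± 4910 CPM. Ribosomal proteins picked by description rose in 100 of 186 cases and fell in 0 (115 and 2 adjusted over the list alone, camera adjusted p = 1.81e-09, adjusted p = 0.789 with an estimated correlation). The ribosome led the GO terms of the higher genes with 136 of 385 (Fisher's exact adjusted p = 7.54e-16). The same ribosomal genes differed between control leaves at 48 and 24 hpi by a median of -0.55. LHY (Psat3g000720) measured 8.34 ± 3.77 CPM in control and 82.3 ± 20 CPM in inoculated leaves. The clock genes TOC1 (Psat4g049800) and ELF4 (Psat5g128480) fell by 1.62 and 3.63 on the log2 scale. Of 8 clock genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.00613, adjusted p = 0.312 with an estimated correlation). In all, 5602 genes were called at 48 hpi, 3318 higher and 2284 lower, and 7733 after subtracting the 0 hpi difference.

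At 72 hpi, isoflavonoid and flavonoid enzymes, extensin and peroxidase stood above the 48 hpi control, and light-harvesting genes stood below it. Extensin-2 (Psat1g095720), a structural cell wall protein, measured 7.65 ± 10.9 CPM in the control (SD, n = 11) and a mean of 1600 CPM in inoculated leaves (n = 12). Its log2 fold change was 7.89 ± 0.81 (SE, edgeR adjusted p = 2.02e-13) and 7.71 after subtraction (limma-voom adjusted p = 0.000333). Pterocarpan synthase 1 (Psat3g067480) reached 90.5 ± 85 CPM (log2 fold change 7.85 ± 1, or 6.4 by limma-voom because 1 control group held 0 counts), with a subtracted value of 6.82 (limma-voom adjusted p = 0.0163). EdgeR called neither subtracted value. Peroxidase P7 (Psat5g250040) reached 61.1 ± 33.2 CPM. A dormancy-associated protein (Psat6g150920) was lower, at 192 ± 84.2 against 3070 ± 691 CPM (log2 fold change -3.97 ± 0.26), with an edgeR subtracted value of -1.94 ± 0.33 (edgeR adjusted p = 1.51e-05).

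All 23 isoflavonoid genes were higher at 72 hpi and 9 after subtraction (23 and 12 adjusted over the list alone, camera adjusted p = 4.91e-19, adjusted p = 0.0939 with an estimated correlation). Of 19 phenylpropanoid genes 18 were higher and 9 after subtraction (18 of the first adjusted over the list alone, camera adjusted p = 3.84e-13, adjusted p = 0.0939 with an estimated correlation). Of 21 flavonoid genes 15 were higher (15 adjusted over the list alone, camera adjusted p = 6.55e-10, adjusted p = 0.0575 with an estimated correlation), and 3 higher and 1 lower after subtraction (3 and 1 adjusted over the list alone). A naringenin dioxygenase (Psat4g099840) measured 0.393 ± 0.47 and 23.9 ± 16.7 CPM. PR genes were higher in 29 of 38 cases and in 6 after subtraction (30 of the first adjusted over the list alone, camera adjusted p = 4.37e-09, adjusted p = 0.186 with an estimated correlation). WRKY genes were higher in 27 of 45 cases and lower in 3 (27 and 3 adjusted over the list alone, camera adjusted p = 1.79e-07, adjusted p = 0.256 with an estimated correlation). After subtraction 6 were higher and 1 lower. Jasmonate and glutathione transferase genes were higher in 8 of 8 and 9 of 9 cases (8 and 9 adjusted over the list alone, camera adjusted p = 9.82e-05 and 4.93e-06, adjusted p = 0.186 and 0.117 with an estimated correlation), and in 3 and 6 cases after subtraction (4 and 7 adjusted over the list alone). The 12-oxophytodienoate reductase (Psat2g190200) measured 8.42 ± 6.05 and 491 ± 200 CPM, with a subtracted value of 6.05 (limma-voom adjusted p = 0.000177) from the same 0 hpi differences. The study chose these members on these samples.

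All 7 photosynthesis genes were lower at 72 hpi (7 adjusted over the list alone, camera adjusted p = 7.69e-06, adjusted p = 0.186 with an estimated correlation), and 0 of 7 were called after subtraction. Chlorophyll a-b binding protein 215 (Psat2g004560) measured 7800 ± 2470 CPM against 33700 ± 9900 CPM, with a subtracted value of -0.82 (limma-voom adjusted p = 0.287). LHY (Psat3g000720) measured 179 ± 58.6 CPM against 8.34 ± 3.77 CPM in the 48 hpi control. In all, 9913 genes were called, 5529 higher and 4384 lower. After subtraction 3242 were called, 1563 higher and 1679 lower. This count was 1459 without inoculated replicate 3 and 1812 without control replicate 2 of every group.

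At 96 hpi, isoflavonoid, phenylpropanoid, PR and WRKY genes stood above the 48 hpi control, and photosynthesis genes stood below it. PR-1C (Psat1g211480) measured 0.832 ± 1.82 CPM in the control (SD, n = 11) and 1100 ± 1210 CPM in inoculated leaves (SD, n = 12). Its log2 fold change was 10.6 ± 1.06 (SE, edgeR adjusted p = 1.97e-13) and 10.25 after subtraction (limma-voom adjusted p = 0.000618). Pterocarpan synthase 1 (Psat3g067480) measured 0.501 ± 0.69 and 569 ± 379 CPM (log2 fold change 10.61 ± 0.98, or 9.5 by limma-voom), with a subtracted value of 9.91 (limma-voom adjusted p = 7.42e-05). EdgeR called neither subtracted value. AB80 (Psat7g091560) fell from 1210 ± 714 to 29.1 ± 38.7 CPM (log2 fold change -6.3 ± 0.56), with an edgeR subtracted value of -4.22 ± 0.66 (edgeR adjusted p = 5.88e-07). Chloroplast carbonic anhydrase (Psat1g058960) fell from 2540 ± 2570 to 106 ± 104 CPM (log2 fold change -4.43 ± 0.59), with a subtracted value of -4.56 (limma-voom adjusted p = 2.09e-06).

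All 23 isoflavonoid genes were higher at 96 hpi and 15 after subtraction (23 and 15 adjusted over the list alone, camera adjusted p = 1.84e-22, adjusted p = 0.0674 with an estimated correlation), with a median log2 fold change of 4.09. Of 19 phenylpropanoid genes 16 were higher and 1 lower, and 10 and 1 after subtraction (17 and 1 of the first adjusted over the list alone, camera adjusted p = 7.5e-12, adjusted p = 0.101 with an estimated correlation). PAL2 (Psat6g182520) measured 4.86 ± 4.53 and 122 ± 82.3 CPM, and 4-coumarate-CoA ligase 4CL3 (Psat2g188920) 10.6 ± 3.8 and 292 ± 194 CPM. Their subtracted values were 4.86 and 3.99 (limma-voom adjusted p = 5.49e-07 and 6.62e-06). Of 21 flavonoid genes 13 were higher (13 adjusted over the list alone, camera adjusted p = 5.12e-08, adjusted p = 0.0674 with an estimated correlation), and 5 higher and 2 lower after subtraction (5 and 2 adjusted over the list alone). PR genes were higher in 28 of 38 cases, and in 10 after subtraction (29 of the first adjusted over the list alone, camera adjusted p = 2.68e-14, adjusted p = 0.105 with an estimated correlation). WRKY genes were higher in 39 of 45 cases and lower in 3, and 23 and 2 after subtraction (39 and 4 of the first adjusted over the list alone, camera adjusted p = 1.1e-12, adjusted p = 0.139 with an estimated correlation). WRKY75 (Psat3g160600) measured 1.17 ± 0.935 and 36.5 ± 18.4 CPM, with a subtracted value of 5.53 (limma-voom adjusted p = 4.38e-05), which edgeR did not call. Such members were chosen by the study on these samples.

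LOX3 (Psat4g168720) and allene oxide synthase (AOS, Psat6g011000), enzymes of jasmonate synthesis, reached 206 ± 90.5 and 78.9 ± 37.9 CPM at 96 hpi, each with a subtracted value of 2 (limma-voom adjusted p = 1.42e-05 and 0.00362). In all 7 of 8 jasmonate genes were higher (7 adjusted over the list alone, camera adjusted p = 0.000531, adjusted p = 0.223 with an estimated correlation), and 5 after subtraction (5 adjusted over the list alone). PAD4 (Psat7g045480), of salicylate signalling, measured 18.2 ± 13.5 and 86.7 ± 21.8 CPM, with a subtracted value of 2.1 (limma-voom adjusted p = 0.000335). Of 9 ethylene genes 8 were higher (8 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.385 with an estimated correlation), and 1 higher and 1 lower after subtraction (1 and 0 adjusted over the list alone). All 7 photosynthesis genes were lower at 96 hpi and all 7 after subtraction (7 of the first adjusted over the list alone, camera adjusted p = 3.81e-10, adjusted p = 0.0939 with an estimated correlation). Thylakoid genes were lower in 81 of 108 cases (Fisher's exact adjusted p = 2e-26), and in 68 of 108 after subtraction (Fisher's exact adjusted p = 1.57e-22). Senescence genes were higher in 6 of 6 cases (6 adjusted over the list alone, camera adjusted p = 0.00669, adjusted p = 0.302 with an estimated correlation), and in 6 after subtraction (6 adjusted over the list alone). On the wall inhibitor list 7 of 10 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.186 with an estimated correlation), and 2 higher and 3 lower after subtraction (4 and 3 adjusted over the list alone). On the clock list 0 of 8 genes were higher at 96 hpi and 5 lower (5 adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.387 with an estimated correlation), and 0 and 4 after subtraction (0 and 4 adjusted over the list alone). LHY (Psat3g000720) measured 8.88 ± 11.4 CPM, against 8.34 ± 3.77 CPM in the 48 hpi control. TOC1 (Psat4g049800) measured 105 ± 21.4 CPM against 309 ± 70.2 CPM, and 94.8 ± 21.9 and 82.8 ± 22.3 CPM in inoculated leaves at 48 and 72 hpi. In all, 11281 genes were called at 96 hpi, 5928 higher and 5353 lower. After subtraction the count was 6678, 2951 higher and 3727 lower.

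**Figure D2:**
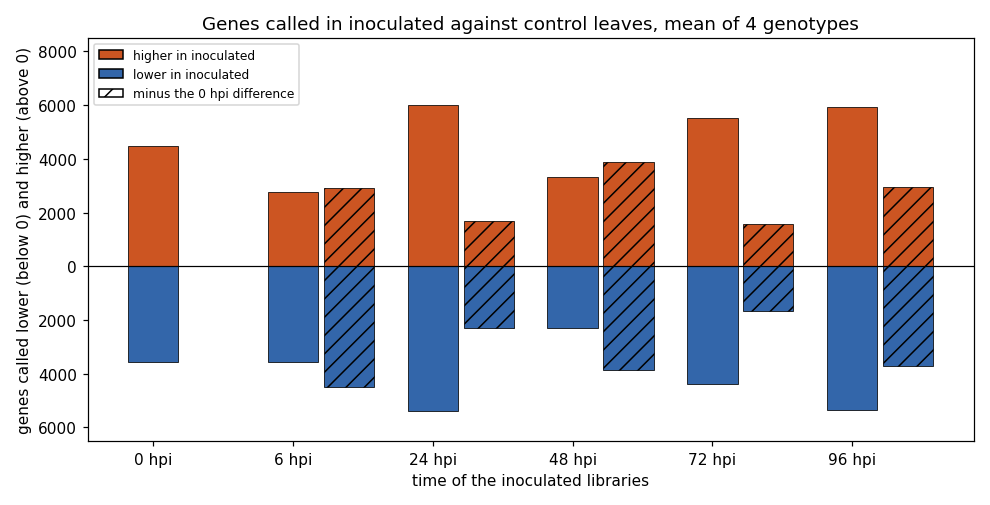
Genes called at an adjusted p under 0.05 in the mean of the 4 genotypes, higher above and lower below the zero line, for each time and for the same comparison minus the 0 hpi difference. The counts run from 5602 genes at 48 hpi to 11396 at 24 hpi before subtraction, and from 3242 to 7733 after it.

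**Figure D3:**
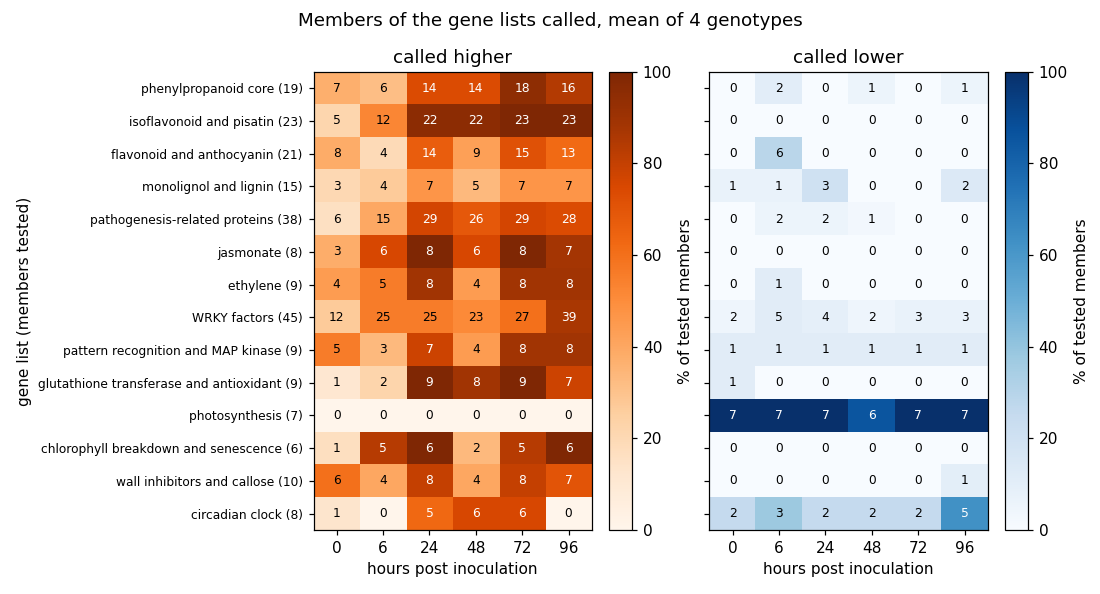
Share of the tested members of each gene list that were called higher and lower in the mean of the 4 genotypes at each time, as a heat map with the number of called members in each cell, for lists with at least 6 members. Of 23 isoflavonoid genes 5 were higher at 0 hpi (9 without the 5 libraries of high share) and 23 at 72 and 96 hpi (9 and 15 after subtraction of the 0 hpi difference).

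The 4 genotypes were compared to ask whether the response to the fungus differed among them. At 24 hpi PGIP1 (Psat3g069920) rose by 10.24 on the log2 scale in OZP1604, 7.39 in WHARTON and 5.44 in TWILIGHT, while its value in 11HP302-12HO-1 was 0.4 (F-test of the difference, edgeR adjusted p = 0.0172). Elongation factor 2 (Psat1g012560) had log2 fold changes of 5.05 in WHARTON, 5.01 in OZP1604, 1.06 in TWILIGHT and 0.72 in 11HP302-12HO-1 (edgeR adjusted p = 0.0172). At 6 hpi the beta subunit of the chaperonin that folds ribulose bisphosphate carboxylase (Psat1g001680) was at -3.25 in TWILIGHT, -1.11 in WHARTON, -0.25 in OZP1604 and 1.7 in 11HP302-12HO-1 (edgeR adjusted p = 3.54e-05). A receptor kinase (Psat6g141840) at 6 hpi had values of -4.24, -1.07, -0.85 and 1.94 in the same order (edgeR adjusted p = 3.54e-05). The beta subunit (Psat1g001680) measured 314, 512 and 54.9 CPM in TWILIGHT controls 1 to 3, and 34.8, 286 and 448 CPM in inoculated replicates 1 to 3 of 11HP302-12HO-1. TWILIGHT control 2 and 11HP302-12HO-1 inoculated 3 lay at -88.86 and -104.68 on the third principal component, against -39.24 to 34.75 for the other 6 hpi libraries of at least 200000 counts. Without these and the 1 library apart at 0 hpi, both genes lost the call (edgeR adjusted p = 0.253 and 0.842). At 96 hpi a strictosidine synthase-like gene (Psat0s1389g0280) was at -2.09 in WHARTON and at 1.51 to 2.93 in the other genotypes (edgeR adjusted p = 0.00654). MAP kinase 19 (Psat4g137000) was at 0.82 in OZP1604 and between -1.28 and -0.42 in the others (edgeR adjusted p = 0.00489). All of these genes lost the call in a fit of the compared libraries alone.

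The F-test of differences among genotypes called 27 genes at 0 hpi, 1394 at 6 hpi, 89 at 24 hpi, 2 at 72 hpi and 24 at 96 hpi. At 48 hpi edgeR called 0 genes, with 1818 at an unadjusted p under 0.05, and limma-voom called 1. The 2 genes at 72 hpi were a cytochrome b5 reductase (Psat5g112400, edgeR adjusted p = 0.038) and a yippee-like protein (Psat2g033720, edgeR adjusted p = 0.0463). Few of these counts held when the test changed, with limma-voom calling 6 genes at 0 hpi, 17 at 6 hpi, 38 at 24 hpi, 0 at 72 hpi and 61 at 96 hpi. Without the 3 apart libraries edgeR called 0 genes at 6 hpi, with 1046 at an unadjusted p under 0.05. It called 5 at 0 hpi and 418 at 24 hpi. That fit kept 11HP302-12HO-1 controls 2 and 3 at 24 hpi, which also lay apart on the third principal component (-118.78 and -79.29). The 6 hpi count was 6 without inoculated replicate 3 of every genotype, 83 without inoculated replicate 2, 243 without control replicate 2 and 4108 without inoculated replicate 1. The 24 hpi count was 1029 without control replicate 1 and 0 without control replicate 3, inoculated replicate 2 or inoculated replicate 3.

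Within single genotypes, PR-1C (Psat1g211480) had log2 fold changes at 96 hpi of 12.56 in OZP1604, 12.37 in WHARTON, 11.19 in TWILIGHT and 6.29 in 11HP302-12HO-1. Those of pterocarpan synthase 1 (Psat3g067480) were 11.62 in OZP1604, 8.68 in TWILIGHT and 8.09 in 11HP302-12HO-1, and in WHARTON the 3 controls held 0 counts. Neither gene was called for a difference among genotypes at 96 hpi (F-test, edgeR adjusted p = 0.832 and 0.827). Counts of called genes from 0 to 96 hpi were 1659, 1699, 7221, 2674, 6598 and 8733 in WHARTON, 3071, 3219, 2103, 1290, 3931 and 5182 in TWILIGHT, and 2583, 2150, 6527, 838, 4046 and 7054 in OZP1604. In 11HP302-12HO-1 they were 2581 at 0 hpi, 586 higher and 347 lower at 6 hpi, 6599 at 24 hpi and then 141, 2265 and 1601. Without the 5 libraries of high share the 0 hpi counts were 375 in TWILIGHT and 9.3e+02 (rounded to 2 digits) in WHARTON. Without the 3 apart libraries TWILIGHT had 1646 and 643 at 0 and 6 hpi. In that fit 11HP302-12HO-1 had 0 at 6 hpi (2157 at an unadjusted p under 0.05 by edgeR) and 212 at 48 hpi. Inoculated replicates 2 and 3 of 11HP302-12HO-1 at 6 hpi lay at 0.16 and 0.12 on a scale from 0 at the control mean to 1 at the inoculated mean of the other genotypes. The 48 hpi controls of 11HP302-12HO-1, used for its last 3 counts, held 33327 to 532772 counts. With the 24 hpi control, 8177 and 8084 genes were called in 11HP302-12HO-1 at 72 and 96 hpi. At 6 hpi in 11HP302-12HO-1, 5 genes were called without the 3 libraries under 200000 counts. Leaving out 1 replicate number of 1 treatment at a time gave counts at 6 and 48 hpi of 0 to 4040 and 18 to 128 in 11HP302-12HO-1, 162 to 2597 and 9.8e+02 to 3053 in WHARTON, 622 to 4714 and 316 to 1202 in TWILIGHT, and 597 to 2823 and 182 to 778 in OZP1604. At 0 hpi the lowest such counts were 9.4e+02, 519, 1361 and 1.0e+03 in 11HP302-12HO-1, WHARTON, TWILIGHT and OZP1604. At 72 and 96 hpi they were 889 and 306 in 11HP302-12HO-1, 2239 and 2865 in TWILIGHT and 2424 and 4534 in OZP1604, and at 24 hpi 1048 in TWILIGHT.

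In control leaves, the clock genes LNK3 and LHY and the UV receptor gene UVR8 differed between times, and a glutathione transferase and an RNA helicase gene among genotypes. LNK3 (Psat4g144600), a partner of clock proteins, measured 121 ± 51.2 CPM at 0 hpi (SD, n = 11) and 1.29 ± 0.576, 3.98 ± 1.91 and 1.84 ± 1.17 CPM at 6, 24 and 48 hpi (edgeR adjusted p = 5.7e-40). LHY (Psat3g000720) went from 625 ± 217 CPM at 0 hpi to 6.45 ± 2.76, 26.9 ± 14.1 and 8.34 ± 3.77 CPM. The UV receptor gene UVR8 (Psat5g040800) measured 311 ± 107 CPM at 0 hpi and 5.75 to 18.1 CPM on average at the later times. The isoflavonoid list differed by a median of 2.51 log2 units between 6 and 0 hpi controls, PR genes by 1.36, monolignol genes by 1.19 and photosynthesis genes by -0.82. Among genotypes, glutathione S-transferase F9 (Psat2g017360) averaged 231 ± 144 CPM in WHARTON (SD, n = 12), 10.6 ± 21.9 in 11HP302-12HO-1 (n = 10), 2.25 ± 3.24 in OZP1604 (n = 12) and 1.84 ± 2.18 in TWILIGHT (n = 12). An RNA helicase gene (Psat0s1018g0120) averaged 27.4 ± 12.3 CPM in OZP1604 and 0.599 to 0.991 CPM in the others. In all, 12791 genes differed among control times and 7615 among control genotypes. The latter was 3765 without control replicate 2 and 4890 without replicate 3 of every group.

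The authors' deposited tables of significant genes were set beside the values here, as 2 analyses of the same libraries. For WHARTON at 96 hpi these hold 5385 genes, of which 5224 were tested here and 4518 called, against 2168.1 by chance. For 11HP302-12HO-1 at 48 hpi, 816 were tested and 19 called, against 5.5 by chance. Over the authors' 24 tables, 84.7% to 100% of the tested genes had 1 sign in both. Their table for 11HP302-12HO-1 at 0 hpi, where a library held 25 counts, lists 1389 genes, 100% higher in inoculated leaves. That at 6 hpi lists 20 genes, 0 higher.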

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

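The test of a library batch marked by the title order was chosen before the result was seen, and the other tests of explanations and of sample splits in this part were chosen only after it.

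Tests of the difference itself called genes whose inoculation response varied among genotypes or from that at 0 hpi. Among genotypes, the edgeR F-test called 27 genes at 0 hpi, 1394 at 6 hpi, 89 at 24 hpi, 2 at 72 hpi and 24 at 96 hpi. The 2 genes at 72 hpi became 0 with limma-voom, with no filter and without the 3 libraries under 200000 counts. Splits of the libraries could not exclude chance at any of these times. Without the 3 apart libraries, 2 of them at 6 hpi, edgeR called 5 genes at 0 hpi and 0 at 6 hpi (1046 at an unadjusted p under 0.05). Against the difference at 0 hpi, edgeR called 7397 genes at 6 hpi, 3972 at 24 hpi, 7733 at 48 hpi, 3242 at 72 hpi and 6678 at 96 hpi. At 6 and 48 hpi the subtraction sets a difference within 1 title set against the 0 hpi difference between both sets, so these counts also hold what separates the sets.

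Other splits of the libraries were counted with limma-trend, the real split among 100. For the averaged comparisons the real split called the most genes (1 of 100 splits as large), which excludes a chance split of these libraries. It called 2463 genes at 0 hpi against a highest other of 437, 4375 at 6 hpi against 3, 10903 at 24 hpi against 1612, 3465 at 48 hpi against 107, 7704 at 72 hpi against 1170 and 9170 at 96 hpi against 76. The same held for the values minus the 0 hpi difference, with 3257 genes at 6 hpi against 1, 1505 at 24 hpi against 84, 2531 at 48 hpi against 3, 655 at 72 hpi against 90 and 2885 at 96 hpi against 370. Control libraries gave 2409 genes among genotypes against 201, and 4849 among times against 40, which excludes chance.

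For the response among genotypes, 21 of 100 splits called as many genes as the real one at 0 hpi (14 genes, highest other 180). This count was 7 at 6 hpi (1 gene, highest other 56), 2 at 24 hpi (113, 174) and 2 at 72 hpi (36, 63). At 48 and 96 hpi it was 1 (12 genes, highest other 3, and 69, 13). These splits also break up differences among control genotypes, so chance is not excluded. At 6 hpi limma-trend called 1 gene where edgeR called 1394.

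Single genotypes have 10 splits of 3 against 3 libraries, too few for a share under 0.05. From 0 to 96 hpi the real splits called 771, 143, 5096, 1777, 5739 and 5640 genes in 11HP302-12HO-1, and the highest others 8, 1776, 19, 5, 12 and 11. In WHARTON they called 63, 559, 6577, 1075, 3289 and 4504, and the highest others 6, 1, 0, 2, 1 and 115. TWILIGHT had 461, 207, 2274, 377, 1755 and 2358 genes against highest others of 5, 4, 9, 1, 2 and 5. In OZP1604 the values were 157, 815, 6130, 277, 1894 and 3664 genes against 15, 4, 7, 6, 5 and 1.

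Inoculated and control leaves already differed at 0 hpi, in 8052 genes by edgeR. The 3 libraries under 200000 counts do not account for this, since 8100 genes were called without them. Without the 5 libraries in which 20 genes took over 40% of the counts, all of them 0 hpi controls, 6591 were called. A library batch marked by the title order would repeat the 0 hpi differences at 24, 72 and 96 hpi, where the treatments also lie in different sets, and not at 6 or 48 hpi. Over the 8052 genes the differences correlated across genes at 0.77 with those at 24 and at 72 hpi, 0.6 with 96 hpi, 0.13 with 6 hpi and -0.19 with 48 hpi, and the 0 hpi comparison shares no library with these. This is consistent with a batch of growth, sampling or library preparation, while a response to handling or inoculation within the sampling time was not tested and stays open.

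In 11HP302-12HO-1 at 6 hpi, splitting control 1, control 3 and inoculated 1 from control 2, inoculated 2 and inoculated 3 gave 1776 genes against 143 for the real split, which points to a structure of the samples other than treatment (2 of 10 splits as large). Over 5601 genes, on a scale from 0 at the control mean to 1 at the inoculated mean of the other genotypes, inoculated replicates 1, 2 and 3 lay at 0.95, 0.16 and 0.12 and controls 1, 2 and 3 at 0.16, 0.07 and 0.3. Exchanged labels of control 2 and inoculated 1 are excluded by the 0.07 of control 2, which would have to lie near 1. Low depth is excluded for inoculated replicate 3, which held 5250006 counts, though replicate 2 held 130308. A single wrong label, an exchange with a library outside this group or a weak response in these leaves may account for it and were not tested.

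Clock genes differed between inoculated and control leaves at 24, 48 and 72 hpi, and at 48 hpi LHY was 9.87 times higher in inoculated leaves within 1 title set, which argues against the library set as the cause. Different hours of harvest for inoculated and control plants would place the differences along the daily course of the control leaves. Over 22 clock genes the 48 hpi differences correlated across genes with the difference between 0 and 6 hpi controls at r = 0.92, with 0.81 for 24 hpi, 0.93 for 72 hpi and 0.32 for 96 hpi. Over all called genes these correlations were -0.19, -0.11, -0.13 and -0.35, but 1 pair of control times cannot exclude harvest hour for them. The clock values are consistent with different hours of harvest, and an effect of infection on the clock was not tested and stays open.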

How the results depend on the processing

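The fits without the 3 libraries under 200000 counts, the 5 libraries of high share (20 genes with over 40% of the counts) or the 3 libraries apart on the principal components, the limma-voom test of the averaged comparisons and the camera test against annotated genes alone were chosen only after the result was seen, and the other settings before. In a fit without 1 replicate number, that replicate of 1 treatment is absent in every genotype and time at once, so each such range mixes several libraries. Counts written as powers of 10, such as 9.4e+02, are rounded to 2 digits. Where a count moved by over 1.5 times, the cause was not tested unless named.

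For the 11 averaged comparisons, counts stayed within 1.5 times of those given under DESeq2's size factors, no filter, the DESeq2 and limma-voom tests, a fit of the compared libraries alone and the absence of the 3 small, the 5 high-share or the 3 apart libraries. Other controls were run only for 72 and 96 hpi before subtraction, where counts also stayed within 1.5 times. The exceptions came from leaving out replicates. The 24 hpi values minus the 0 hpi difference ranged from 2083 genes (without inoculated replicate 3) to 3860, and those at 72 hpi from 1459 (without inoculated replicate 3) to 2748. DESeq2's size factors moved 0 of the 43 counts and the DESeq2 test 0 of 35 by over 1.5 times.

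Single genotypes depended more on the libraries in the fit. With only the compared libraries, which leaves fewer residual degrees of freedom, 11HP302-12HO-1 had 4702 genes at 0 hpi, 0 at 6 hpi (1398 at an unadjusted p under 0.05 by edgeR, 143 called by limma-trend), 2370 at 24 hpi and 1277 at 72 hpi. WHARTON had 218 at 0 hpi, 2824 at 6 hpi and 5288 at 96 hpi, TWILIGHT 786, 38 and 9.3e+02 at 0, 6 and 24 hpi, and OZP1604 584 and 3 at 0 and 6 hpi. With the 24 hpi control, 11HP302-12HO-1 had 8177 genes at 72 hpi and 8084 at 96 hpi, and with the mean of the controls 6886 and 6988. Without its 3 small libraries these were 8258, 8170, 6829 and 6944, and it had 5 genes at 6 hpi and 80 at 48 hpi. The mean of the controls gave TWILIGHT 7265 and 9017 genes at 72 and 96 hpi (7319 and 9184 without the small libraries) and OZP1604 7104 at 72 hpi (7200). Without the 5 high-share libraries, which leaves 1 TWILIGHT control at 0 hpi that is assumed to vary like the other groups, WHARTON had 9.3e+02 and TWILIGHT 375 genes at 0 hpi, and the F-tests 6 at 0 hpi and 47 at 24 hpi. Without the 3 apart libraries 11HP302-12HO-1 had 0 genes at 6 hpi (2157 at an unadjusted p under 0.05 by edgeR) and 212 at 48 hpi. There TWILIGHT had 1646 and 643 at 0 and 6 hpi, and the F-tests 5, 0 and 418 at 0, 6 and 24 hpi. None of the 3 is in the 48 hpi comparison or the 24 hpi F-test, which share with them the filter, the scaling and the estimate of the spread.

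Leaving out a replicate number gave ranges of 9.4e+02 to 2568 genes at 0 hpi, 0 to 4040 at 6 hpi, 18 to 128 at 48 hpi, 889 to 2003 at 72 hpi and 306 to 1423 at 96 hpi in 11HP302-12HO-1. WHARTON ranged from 519 to 1694 at 0 hpi, 162 to 2597 at 6 hpi and 9.8e+02 to 3053 at 48 hpi. For TWILIGHT the ranges were 1361 to 2861, 622 to 4714, 1048 to 1778, 316 to 1202, 2239 to 3124 and 2865 to 4407 from 0 to 96 hpi. OZP1604 ranged from 1.0e+03 to 2113 at 0 hpi, 597 to 2823 at 6 hpi, 182 to 778 at 48 hpi, 2424 to 3294 at 72 hpi and 4534 to 7147 at 96 hpi.

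The genotype F-tests changed with almost every setting. No filter gave 44 genes at 24 hpi and 0 at 72 hpi. With limma-voom 6, 17, 38, 1, 0 and 61 genes were called from 0 to 96 hpi, and in a fit of the compared libraries 2, 0, 6, 2, 0 and 7. Leaving out a replicate number gave 0 to 42 genes at 0 hpi, 6 to 4108 at 6 hpi, 0 to 1029 at 24 hpi, 0 to 4 at 48 hpi, 0 to 42 at 72 hpi and 0 to 26 at 96 hpi. The 24 hpi control gave 233 genes at 72 hpi and 1.0e+03 at 96 hpi, and the mean of the controls 6 and 300. Without the 3 small libraries there were 2 genes at 48 hpi and 0 at 72 hpi, then 200 and 1091 with the 24 hpi control and 6 and 250 with the mean of the controls. The settings with 0 genes had between 1046 and 3221 genes at an unadjusted p under 0.05. Control libraries differed among genotypes in 3765 (without control replicate 2) to 7479 genes.

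Replicate numbers did not pair the libraries: same-numbered inoculated and control libraries had a mean correlation of 0.019 in their deviations, 13 of 39 were over 0.1, and all 3 were over 0.1 in 1 of 13 sets. With the replicate block, 36 of 43 counts stayed within 1.5 times. Those that moved were 1580 and 263 genes in 11HP302-12HO-1 at 0 and 6 hpi, and the genotype F-tests with 8, 328, 0, 5 and 1 genes at 0, 6, 24, 48 and 72 hpi. The 0 at 24 hpi, by edgeR, had 3139 genes at an unadjusted p under 0.05, and limma-voom without the block called 38.

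Of the 84 pairs of a fixed list and an averaged comparison, camera called 64 with the preset correlation, 58 against annotated genes alone and 0 with an estimated correlation, where 23 had an unadjusted p under 0.05. Among 2107 values of the genes named, 2008 kept their direction and their side of the threshold, 66 lost the call, 30 gained it and 3 changed sign. The changes of sign were in uncalled values, L12-3 (Psat7g228520) at 24 hpi minus 0 hpi, from 0.17 to -0.02 without control replicate 1 and -0.01 without the 5 high-share libraries, and LHY (Psat3g000720) at 96 hpi, from -0.6 to 0.23 without control replicate 2. All 8 genes named for genotype differences lost the call in a fit of the compared libraries, and the 2 at 6 hpi also without the 3 apart libraries. At 6 hpi the protease inhibitor, the beta-1,3-glucanase and the sucrose transporter lost it without inoculated replicate 1, and at 96 hpi expansin-A8 without control replicate 2. The 12-oxophytodienoate reductase lost its subtracted calls at 24 and 72 hpi in edgeR without control replicate 1 or 3, without the 5 high-share libraries and in a fit of the compared libraries. For PR-1C, pterocarpan synthase 1, extensin-2 and WRKY75 edgeR did not call the subtracted values that limma-voom called, and each had 0 counts in at least 1 whole group.

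The 11HP302-12HO-1 results at 48, 72 and 96 hpi rest on control libraries of 33327, 396976 and 532772 counts. There edgeR called 141, 2265 and 1601 genes and limma-trend 1777, 5739 and 5640, and what depth contributes was not tested.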

Other observations

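The 17 wider gene lists drawn from words in the descriptions, and the tests on them, were chosen only after the data were seen. Their members come from the study's own tables, and over the 6 averaged comparisons none of their camera calls held with an estimated correlation (lowest adjusted p = 0.319).

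Genes of heat shock proteins rose at 6 and 48 hpi, and those of resistance proteins were divided. Heat shock proteins, which keep other proteins folded under stress, rose in 42 of 79 cases and fell in 5 at 6 hpi (camera adjusted p = 1.07e-10, adjusted p = 0.789 with an estimated correlation), and 37 rose and 8 fell at 48 hpi (camera adjusted p = 0.000348, adjusted p = 0.789 with an estimated correlation). The 18.2 kDa class I heat shock protein (Psat7g115480) rose from 2.85 ± 3.97 CPM (SD, n = 12) to 59.4 ± 114 CPM (SD, n = 11) at 6 hpi, a log2 fold change of 3.93 ± 0.51 (SE, edgeR adjusted p = 4.76e-09). Among 78 genes described as nucleotide-binding leucine-rich repeat (NLR) resistance proteins, the intracellular receptors of pathogen effectors, 12 rose and 8 fell at 6 hpi and 13 rose and 8 fell at 48 hpi (camera adjusted p = 0.276 and 0.61). RPV1 (Psat2g115400) rose from 7.64 ± 3.9 to 50.7 ± 16.7 CPM at 6 hpi (edgeR adjusted p = 3.68e-08) and from 1.32 ± 1.04 to 16.6 ± 7.6 CPM at 48 hpi. At 96 hpi 37 NLR genes were higher and 10 lower than in the 48 hpi control (camera adjusted p = 0.000234, adjusted p = 0.789 with an estimated correlation), against 11 and 13 after subtracting the 0 hpi difference. The NLR gene Psat2g013360 reached 87.8 ± 43.7 CPM against 2.6 ± 3.43 CPM, with a subtracted log2 value of 3.57 by limma-voom (limma-voom adjusted p = 0.00391) and 2.65 by edgeR (edgeR adjusted p = 0.156).

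Receptor kinases were higher in 178 of 304 cases and lower in 50 at 96 hpi (camera adjusted p = 4.55e-10, adjusted p = 0.746 with an estimated correlation), and in 71 and 54 after subtraction. At 6 hpi 67 rose and 57 fell. Peroxidases and laccases, enzymes that cross-link the cell wall, rose in 16 of 51 cases and fell in 7 at 6 hpi, and rose in 23 and fell in 3 at 48 hpi (camera adjusted p = 3.51e-10, adjusted p = 0.482 with an estimated correlation). Of 39 chitinase and glucanase genes 10 rose and 6 fell at 6 hpi, and 22 were higher and 3 lower at 72 hpi (camera adjusted p = 7.44e-05, adjusted p = 0.741 with an estimated correlation). At 0 hpi 16 were higher and 2 lower, and at 72 hpi 3 and 2 after subtraction. Class V chitinase CHIT5a (Psat0s5923g0040) measured 1.91 ± 1.43 CPM in the 48 hpi control and 80.3 ± 35.5 CPM at 96 hpi, with a subtracted log2 value of 4.32 (limma-voom adjusted p = 1.48e-08).

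At 6 and 96 hpi, genes of the cuticle and of water transport were lower in more cases than higher, and wall-loosening and ribosomal protein genes were divided at 96 hpi before subtraction. Epidermis and cuticle genes fell in 31 of 71 cases and rose in 8 at 6 hpi (camera adjusted p = 7.44e-05, adjusted p = 0.789 with an estimated correlation). At 96 hpi 27 were lower and 13 higher, and 33 and 4 after subtraction. At 0 hpi 32 were higher and 3 lower, or 23 and 1 without the 5 libraries of high share. ECERIFERUM 2 (Psat3g007800), which acts in wax synthesis, fell from 25.1 ± 13.8 to 5.44 ± 3.52 CPM at 48 hpi (edgeR adjusted p = 4.18e-05). Of 17 aquaporins, the water channels of cell membranes, 10 were lower and 1 higher at 96 hpi (camera adjusted p = 0.000521, adjusted p = 0.789 with an estimated correlation), and 10 and 0 after subtraction. At 6 hpi 4 were lower and 0 higher, and at 0 hpi 1 lower and 3 higher. PIP2-7 (Psat7g228600) measured 130 ± 124 CPM in the 48 hpi control and 15.9 ± 10.5 CPM at 96 hpi, with a subtracted value of -3.23 (limma-voom adjusted p = 5.29e-06). Of 17 wall-loosening genes 5 were lower and 4 higher at 96 hpi, and 8 and 2 after subtraction, with expansin-A8 (Psat5g150120) at 42.3 ± 45.7 and 2.05 ± 3.52 CPM. Of 16 vascular genes by description 8 were lower and 2 higher at 96 hpi, and 11 and 1 after subtraction. Of the 8, cellulose synthase CesA3 (Psat0s2215g0280), known from the primary walls of growing cells, fell by 2.43 on the log2 scale. Cell cycle genes fell in 15 of 112 cases and rose in 4 at 6 hpi, and fell in 20 and rose in 6 at 48 hpi (camera adjusted p = 0.00179, adjusted p = 0.789 with an estimated correlation). Of 186 ribosomal protein genes 51 were higher and 36 lower at 96 hpi, and 110 and 0 after subtraction.

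Several fixed lists held few tested members, all chosen by the study on these samples. The vascular marker, a sucrose transporter (Psat1g098880), measured 540 ± 289 and 1060 ± 314 CPM at 6 hpi, a log2 fold change of 0.88 ± 0.28 (edgeR adjusted p = 0.0098), and 327 ± 227 and 770 ± 318 CPM at 24 hpi. Of 2 seed and nodule genes 1 was higher at 6 hpi and 0 at 48 hpi. The fixed lists for the cell cycle, meristem, epidermis and cytosolic ribosome had 0 tested members. Monolignol genes rose in 4 of 15 cases and fell in 1 at 6 hpi, and were higher in 7 and lower in 2 at 96 hpi. Dehydration and abscisic acid genes by description were divided, with 13 higher and 15 lower of 85 at 6 hpi.

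The first principal component held 29.1% of the variance, of which 58.3% lay between times and 22.7% between the title sets, and the second 16.1%, of which 70.9% lay between times and 56.9% between the sets.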
